A study of Mus musculus with 23 samples.

How the data were processed

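RNA of sorted mouse CD4+ T cells was measured on Affymetrix M430v2 arrays, 23 in all, in 9 groups of 2 to 4 arrays. Per the labels, RNA was isolated with Trizol and amplified by 2 rounds of the MessageAmp kit. The deposited values are in the unit intensity: the authors ran the RMA algorithm in GenePattern, whose version is not given. The values lie on a linear scale, from 4.706 to 26750 in the table, and log2 was taken of them with no pseudocount. Median intensities of the arrays ran from 63.7 to 81.1 and upper quartiles from 157 to 254, so the arrays do not share 1 distribution. No scan dates are given, so no array batch could be looked for by date.

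Annotation named 34945 of the 45101 probe sets by 1 gene symbol, with the 64 control probe sets left out. The 932 probe sets with several symbols and the 9211 without a symbol, controls included, were not used. The Entrez identifier of 34741 named probe sets was in the gene table, and 0 symbols were updated. This gave 18193 genes, of which 9010 had several probe sets; the probe set with the highest mean over all arrays stood for the gene. A gene was tested when the mean of at least 1 group exceeded the median of all values, 77.0 intensity units or 6.27 on the log2 scale, which left 12516 genes. Some listed genes have no probe set that is named alone and are not reported.

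A linear model with a mean for each of the 9 groups was fitted to all 23 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes), which left 14 residual degrees of freedom and added 3.48 from the prior. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. A gene is called past the threshold when its Benjamini-Hochberg adjusted p, over the 12516 genes of that comparison, lies under 0.05. All tests are two-sided. Log2 fold changes are of the first group named over the second and carry their standard error; levels are group means in log2 intensity with the standard deviation between arrays. Where the lower group mean lay below the filter, as in 78 of 290 named and called results, background can hold up the lower value, so such a fold is given as "at least" and its log2 fold change is a lower bound too. The comparisons were LP Treg with LP Tconv, homeostatic Foxp3+ with Foxp3-, DEC CD25+ with CD25-, the 3 pairs among the lymph node subsets, and LP Treg with the CD103-Klrg1- and with the CD103+Klrg1+ lymph node subset. The difference between the first 3 of these was tested gene by gene as an interaction.

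Each array holds RNA pooled from several mice, 4 to 6 for the gut and lymph node groups, 2 to 3 for the homeostatic groups and 5 to 10 for the DEC groups. The spread between arrays is therefore a spread between pools and says little about single mice. The small number of arrays limits the precision of every value. The labels do not say whether arrays of 2 groups with the same replicate number came from the same pool of mice. In residuals from the group means, correlation between same-number arrays across genes was 0.66, 0.58 and 0.49 in the homeostatic groups, and all other pairs were negative. In the DEC groups it was 0.39, 0.51 and 0.38, and the other pairs lay from -0.59 to 0.12. Residuals cancel out within a group, so positive same-number values force the other pairs to be negative on balance. The negative pairs therefore add no support. From the positive values the numbers were read as pairs in both, an assumption that the labels do not settle. The result with the replicate number as a block therefore stands beside the unblocked one. The gut and lymph node groups have 2 numbers only, and their blocked results stand with the other alternatives. Same-number residuals of the LP groups correlated at -0.07, so their block has no backing there. For LP Treg with the lymph node subsets the block also tied gut to lymph node arrays of the same number. That pairing is assumed and was not checked.

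The rule for named genes took the genes of the sort markers (Foxp3, Il2ra for CD25, Itgae for CD103, Klrg1) in each comparison. It added the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the groups, with 5 and 5 in 2 of the comparisons. For interactions it took the 5 smallest p, for each list up to 4 members with the smallest p and any called member moving against its list, and for the overlap up to 15 genes. Clone names and variable segments of receptors were counted but not named. In each comparison all called genes had arrays that did not overlap between the groups, except homeostatic, where 218 of 220 did; with 2 against 2 arrays this is a weak criterion. The comparisons, the rule, the gene lists and the alternatives were fixed before the data were examined.

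The 27 gene lists, with the tested members in brackets, were Treg signature (34), Conventional T cell genes lower in Treg (17), Effector and memory-like T cell genes (23), Naive and central T cell genes (16), Cell cycle (41), Th17 (11), Th1 (12), Th2 (5), Follicular helper genes (10), Cytotoxic granule and killer receptor genes (11), Chemokine receptors (15), Integrins and adhesion (16), TNF receptor and costimulatory genes (21), Immediate early and T cell receptor induced genes (28), Heat shock (10), Interferon-induced (29), Glycolysis (13), Cholesterol synthesis (13) and TGF-beta pathway genes (15). Markers of other cells were B cell (10), plasma cell (6), myeloid and dendritic cell (21), CD8 T and NK cell (7), intestinal epithelium (6), stromal (8), erythroid (3) and mast cell (5). The lists were written from general knowledge and share members: 13 of the 34 Treg signature genes stand in another list, and it holds the 4 sort genes, so its shift is not independent of the sort. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Camera asks whether a list moves more than other genes do. The test named fry asks in its directional form whether the members move, on balance, one way, and in its mixed form whether they change either way, and compares them with no other genes. Of the 216 tests, 89 passed with camera at the preset correlation, 35 with an estimated correlation and 47 with fry.

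Alternatives were no filter, a filter at the 65th percentile, the mean of all probe sets of a gene, quantile and cyclic loess normalization, a pseudocount of 16, a fit of each comparison's own groups, a prior with intensity trend and robust estimation, array weights, the replicate block, and leaving out each array in turn. Leaving out both dim DEC CD25- arrays was added after the data were seen. The fit was tested on simulated data with the same design, in which 100 genes were changed by 2-fold and 100 by 4-fold. It recovered 40% and 81% of these for LP Treg with LP Tconv, 48% and 94% for the homeostatic and 59% and 93% for the DEC groups, 30% and 77%, 32% and 79% and 37% and 82% for the lymph node pairs, and 41% and 86% and 34% and 88% for LP Treg with the lymph node subsets. Recovery was lower for the interactions, 19% and 66% (LP against homeostatic), 12% and 68% (LP against DEC) and 21% and 73% (homeostatic against DEC). False calls ranged from 5 of 124 to 10 of 104. No call had the wrong sign. A Cell cycle shift of 0.7 planted in simulated data was the 1 list called of 27. These simulated data held independent noise, with 1 spread per gene for all arrays and no pairs. The real arrays differ in spread, with array weights from 0.13 to 4.56, and genes of a list can move together. The simulated rates therefore need not hold for the real data.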

Results

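Regulatory T (Treg) cells, CD4+ T cells that carry the transcription factor Foxp3 and restrain immune responses, were compared with other CD4+ T cells and with each other across sites and origins. Cells from C57BL/6 mice with a Foxp3-GFP reporter gave 5 groups of 2 arrays each. GFP+ cells (LP Treg) and GFP- cells (LP Tconv) came from the small intestinal lamina propria (LP), the tissue under the gut epithelium. Peripheral lymph nodes (LN) gave Treg cells sorted by CD103, the integrin chain encoded by Itgae, and by the receptor Klrg1, as CD103-Klrg1-, CD103+Klrg1- and CD103+Klrg1+ subsets. The other groups held cells that had started out as non-Treg cells and were sorted after transfer. Homeostatic groups, of 3 arrays each, were GFP+ and GFP- cells recovered from spleen and lymph nodes 14 days after GFP- cells of BDC2.5 T cell receptor transgenic NOD mice entered NOD RAG-/- hosts, which make no T or B cells of their own. DEC groups were CD25+ (3 arrays) and CD25- (4 arrays) cells recovered 3 weeks after CD25- cells of HA6.5 transgenic Balb/c RAG-/- mice entered Balb/c hosts that got 1 injection of 50 ng DEC-HA peptide. The DEC cells were sorted by CD25, not by Foxp3.

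Array medians ran from 63.7 to 81.1 intensity units. DEC CD25- replicates 3 and 4 had the lowest, 68.5 and 63.7, and mean correlations with their own group of 0.933 and 0.947. In replicate 3 the 3' Gapdh probe set exceeded the 5' one by 6.59 on the log2 scale, a sign of RNA shortened from its 5' end, against 3.13 in replicate 1. The 2 LP Tconv arrays correlated at 0.963, the lowest of the groups of 2, and differed in these signs: the 3' probe set exceeded the 5' one by 3.17 and 1.63 for Gapdh and by 2.14 and 0.80 for Actb. All mice were labelled male. Xist, a transcript of the inactive X chromosome of females, lay between 11.85 and 13.25 on the 7 DEC arrays and between 6.47 and 7.67 on the other 16.

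Foxp3 averaged 11.21 ± 0.18 in LP Treg, 10.42 ± 0.0714 in homeostatic Foxp3+ and 10.47 ± 0.0852 in DEC CD25+ arrays, and from 10.35 to 11.20 in the lymph node subsets. It was at 4.65 ± 0.11 in LP Tconv and 4.76 ± 0.05 in homeostatic Foxp3- arrays, near the floor, but at 7.97 ± 0.71 in DEC CD25- arrays.

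**Figure D1:**
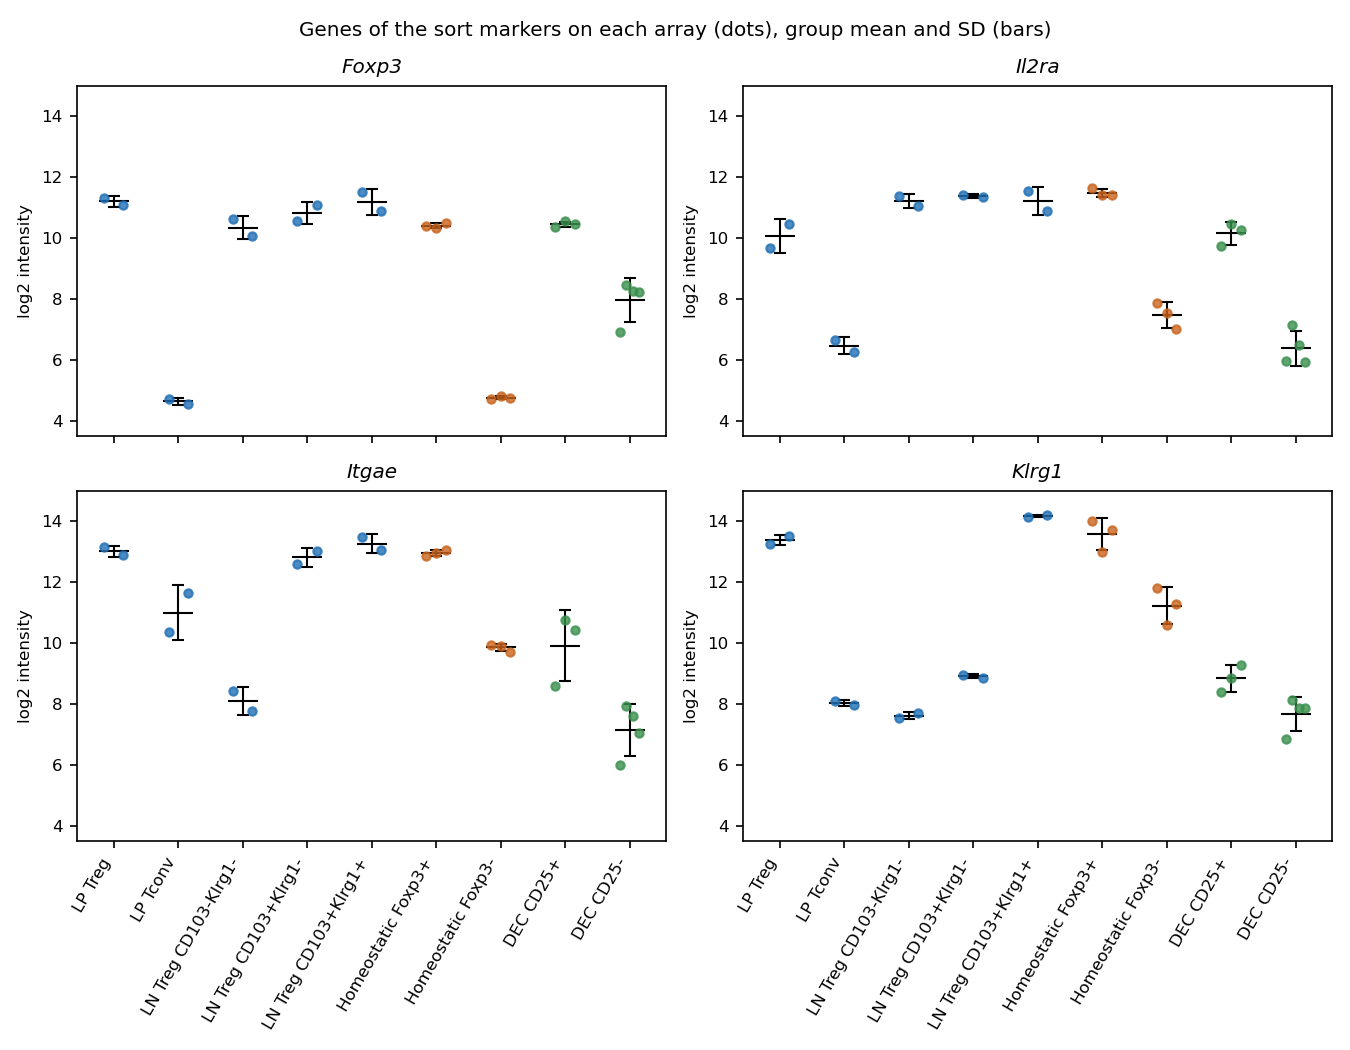
Log2 intensity of Foxp3, Il2ra, Itgae and Klrg1 in the 9 groups, with a dot for each array and a bar for the group mean with its standard deviation. Foxp3 lies at 4.65 and 4.76 in the groups sorted as GFP- and at 7.97 in DEC CD25- arrays.

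LP Treg with LP Tconv arrays asked what sets Treg cells of the gut apart from their Foxp3- neighbours. In LP Treg cells Foxp3 was at least 94.4-fold higher (6.56 ± 0.36 on the log2 scale, n = 2 and 2 arrays, limma adjusted p = 1.16e-08), and Itgb8, an integrin chain that activates TGF-beta, was at least 88-fold higher (6.46 ± 0.48). Il2ra, a chain of the high-affinity IL-2 receptor, Il10, an anti-inflammatory cytokine, and Gpr15, a gut homing receptor, rose by 3.60 ± 0.38, 3.98 ± 0.50 and 4.00 ± 0.38. Klrg1 rose by 5.34 ± 0.41, while Itgae differed by 2.01 ± 0.61 and did not pass the threshold (adjusted p = 0.113), though it did with the mean of probe sets (adjusted p = 0.0485) and with the replicate block (adjusted p = 0.00458). LP Tconv cells held more of the inflammatory cytokines Il21 (-4.99 ± 0.70) and Il17a (-4.25 ± 0.33), of the granzyme Gzmk (-3.87 ± 0.45) and of the death ligand Fasl (-3.65 ± 0.50).

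The test called 338 of 12516 genes, 177 higher and 161 lower in LP Treg cells, and 315 differed by at least 2-fold. The other large rises were Cd83 (4.56 ± 0.49), Neb (4.31 ± 0.30), Ky (3.84 ± 0.25), Fmnl2 (3.62 ± 0.61) and Gpr83 (3.62 ± 0.35). The other large falls were those of the cyclic nucleotide phosphodiesterases Pde3b (-4.61 ± 0.53) and Pde7a (-3.83 ± 0.28) and of Pxylp1 (-3.65 ± 0.39), Sema4a (-3.48 ± 0.42), Xcl1 (-3.45 ± 0.46) and Lypd6b (-3.42 ± 0.37). Adjusted p of these genes ran from 1.16e-08 to 0.00153.

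Of the 34 Treg signature genes 20 rose and 0 fell (28 rose when adjusted over the list alone), with a median of 1.83 (camera adjusted p = 7.24e-57). Ikzf2, which encodes Helios, rose by 2.82 ± 0.18. Of 21 TNF receptor and costimulatory genes 7 rose, among them Tnfrsf4 (2.75 ± 0.29) and Tnfrsf9 (3.18 ± 0.40), with 9 higher and 2 lower when adjusted over the list alone (adjusted p = 8.87e-08). Of 17 conventional T cell genes 6 fell, such as Themis (-2.68 ± 0.28) and Il2 (-2.09 ± 0.23), and 1, Nrip1, rose (1.81; 12 fell when adjusted over the list alone; adjusted p = 4.11e-14). The naive and central list moved down (median -1.05, adjusted p = 4.22e-08), with 2 members fallen, Rasgrp2 (-1.33) and Igfbp4 (-2.23), and 9 when adjusted over the list alone.

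Genes of inflammatory helper cells were lower in LP Treg cells. Of 11 Th17 genes 6 fell (adjusted p = 3.64e-12), and of 12 Th1 genes 6 fell (8 when adjusted over the list alone; adjusted p = 3.64e-12), with Ifng (-2.87 ± 0.41) and Il18r1 (-2.28 ± 0.27) among them. Of 11 cytotoxic genes 5 fell, for example Nkg7 (-2.54 ± 0.48) and Ctsw (-2.54 ± 0.51) (adjusted p = 1.98e-06). The Th2 list moved up (median 1.08, adjusted p = 0.00632): of 5 tested members the chemokine receptors Ccr4 (1.75 ± 0.23) and Ccr8 (1.87 ± 0.31) rose and the Th2 cytokine Il4 (-1.01 ± 0.22) fell. All of these list calls held with an estimated correlation, and that of the Th2 list ended without LP Tconv replicate 2 (adjusted p = 0.0609). The immediate early list (median 0.44, 0 members called) and the CD8 T and NK cell markers (median -0.0573, with Klrd1 and Xcl1 fallen) passed with camera only, with adjusted p = 0.814 and 0.378 with an estimated correlation.

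The number of called genes depended on single arrays, with 173 without LP Treg replicate 1 and 513 without LP Tconv replicate 1, and on the fit, with 17 when the 4 arrays were fitted alone. It was 557 without both dim DEC CD25- arrays, which enter through the pooled spread only. This alternative was chosen after the data were seen. With array weights, which were 0.36 for both LP Tconv arrays, the count was 221. For arrays that vary more than the pooled spread p runs small, so p of this comparison can be too small.

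**Figure D2:**
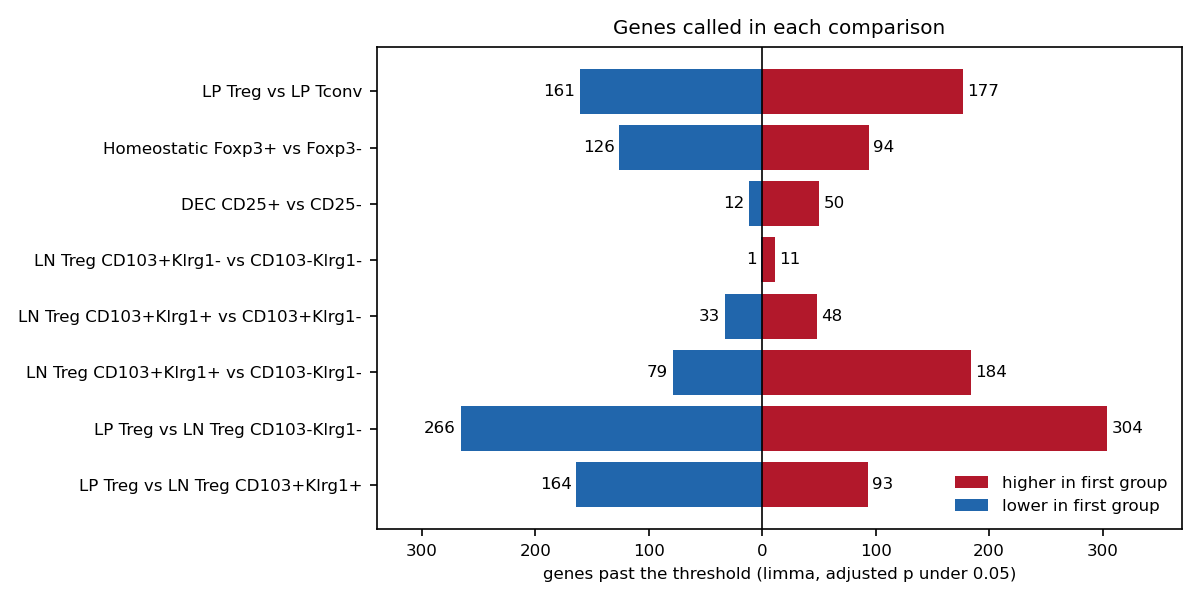
Number of genes past the limma threshold in each of the 8 comparisons, with bars to the right for genes higher in the group named first and to the left for genes lower in it. The counts range from 12 between the CD103+Klrg1- and CD103-Klrg1- lymph node subsets to 570 between LP Treg and CD103-Klrg1- lymph node Treg cells.

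Homeostatic Foxp3+ with Foxp3- arrays asked what distinguishes cells that had gained Foxp3 in lymphopenic hosts from those that had not. Foxp3 was at least 50.4-fold higher in the converted cells (5.66 ± 0.30, n = 3 and 3 arrays, adjusted p = 4.67e-09) and Il2ra 16-fold higher (4.00 ± 0.31). The granzyme Gzmb rose by 3.83 ± 0.26, the inhibitory receptor Ctla4 by 3.06 ± 0.60, Itgae by 3.09 ± 0.50 and Klrg1 by 2.35 ± 0.33. The cells that stayed Foxp3- held more Tnfsf14 (-3.88 ± 0.26), a TNF family ligand also named LIGHT, more of the chemokine receptor Cxcr6 (-3.37 ± 0.37) and more Pde3b (-2.96 ± 0.43).

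Of the 220 called genes 94 were higher and 126 lower in Foxp3+ cells, and 180 differed by at least 2-fold. With the replicate number as a block the test called 480. The other large rises were Neb (3.93 ± 0.25), Nxpe4 (3.36 ± 0.38), Itih5 (3.33 ± 0.34) and Dusp4 (3.22 ± 0.63) and the immunoglobulin heavy chain gene Ighm (3.21 ± 0.40). The other large falls were Tdrp (-3.02 ± 0.42), Gpm6b (-2.98 ± 0.70), Arfgef3 (-2.96 ± 0.22), Ryr1 (-2.95 ± 0.19), Pde7a (-2.91 ± 0.23), Ppic (-2.80 ± 0.26) and Ube2e2 (-2.74 ± 0.28). Adjusted p of these genes ran from 4.67e-09 to 0.0341.

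Of 34 Treg signature genes 16 rose and 0 fell (19 rose when adjusted over the list alone), with a median of 1.05 (adjusted p = 8.04e-35). Of 10 follicular helper genes 3 fell (4 when adjusted over the list alone; adjusted p = 3.80e-06): Bcl6, the transcription factor that defines these helper cells (-1.64 ± 0.31), the inhibitory receptor Pdcd1 (-2.28 ± 0.43) and Tox2 (-2.52 ± 0.55). Both lists held with an estimated correlation. Members of the cell cycle list lay higher together (median 0.70, adjusted p = 1.40e-20), though 0 of 41 passed over all genes and 4 when adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.164).

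Further list calls were lost with an estimated correlation. Conventional T cell genes moved down (3 of 17 fell, with Il2 (-1.05 ± 0.19) and Tgfbr3 (-2.61 ± 0.51); adjusted p = 0.206 with an estimated correlation), as did Th17 genes (3 of 11 fell; adjusted p = 0.164 with an estimated correlation). In the cytotoxic list Gzmb rose while Gzma (-2.01 ± 0.34) and Klrd1 (-2.53 ± 0.59) fell (adjusted p = 0.269 with an estimated correlation). CD8 T and NK markers lay lower on the Foxp3+ array in each numbered pair (6.68 and 7.56, 7.67 and 7.93, 7.20 and 7.55), a shift that camera did not call (adjusted p = 0.148). Glycolysis genes moved up, with Slc2a3 (1.09 ± 0.23), a glucose transporter, and Hk2 (1.00 ± 0.25), hexokinase, called (adjusted p = 0.536 with an estimated correlation). The TNF receptor list moved up, with 4 members risen and 1, Pdcd1, fallen (adjusted p = 0.354 with an estimated correlation), and its camera call also ended with the block, with adjusted p = 0.101. Heat shock genes moved up (median 0.17, 0 called; adjusted p = 0.349 with an estimated correlation), and this call ended with quantile normalization (adjusted p = 0.0543). Myeloid and dendritic markers moved down (median -0.37, 0 called; adjusted p = 0.626 with an estimated correlation), with adjusted p = 0.0543 after quantile normalization. With the block, erythroid markers were called lower in Foxp3+ arrays (median -0.67, adjusted p = 0.000216), against adjusted p = 0.175 without it. Myeloid transcripts were abundant in both groups: Lyz2, lysozyme of myeloid cells, averaged 10.58 ± 1.06 in Foxp3+ and 11.24 ± 0.94 in Foxp3- arrays, against 6.88 ± 0.23 in LP Treg arrays. Cells with CD11b or CD11c had been sorted out by the labels; whether RNA of host cells enters the homeostatic differences was not tested.

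Leaving out 1 array changed the count to 142 without Homeostatic Foxp3+ replicate 1, 133 without Homeostatic Foxp3+ replicate 3 and 135 without Homeostatic Foxp3- replicate 1. It was 741 when the 6 arrays were fitted alone and 435 without both dim DEC CD25- arrays.

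DEC CD25+ with CD25- arrays asked the same of cells that had met their antigen as a peptide aimed at dendritic cells. Il2ra, the gene of the sort marker, was 13.6-fold higher in CD25+ cells (3.77 ± 0.29, n = 3 and 4 arrays, adjusted p = 1.58e-06), Itgae 6.81-fold (2.77 ± 0.47) and Foxp3 5.62-fold (2.49 ± 0.28). The Treg genes Gpr83, Itgb8 and Ikzf4, which encodes the transcription factor Eos, rose by 2.46 ± 0.27, 2.26 ± 0.37 and 2.18 ± 0.31. CD25- cells held more Sema4a (-2.07 ± 0.32) and more of the IL-7 receptor chain Il7r (-0.97 ± 0.17). Klrg1 differed by 1.17 ± 0.31 and did not pass the threshold (adjusted p = 0.123), but was called with the replicate block (1.24, adjusted p = 0.0057).

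Of the 62 called genes 50 were higher and 12 lower, and 54 differed by at least 2-fold; with the replicate number as a block the test called 139. The median over all genes stood at 0.16 and moved to -0.0501 with quantile and -0.0235 with cyclic loess normalization. The counts then became 42 higher and 37 lower with the first and 38 and 34 with the second, so the share called higher, 80.6%, fell to 53.2% and 52.8%. The other large rises were Itih5 (2.57 ± 0.32), H2-Ob (2.48 ± 0.35), Phlpp1 (2.12 ± 0.14) and Inpp4b (2.11 ± 0.43). The other large falls were Tdrp (-1.82 ± 0.39), Lypd6b (-1.77 ± 0.29), Il1rl2 (-1.60 ± 0.24), Ldlrad4 (-1.29 ± 0.27), Man1c1 (-1.26 ± 0.24), Tex15 (-1.08 ± 0.18), Fam78a (-1.01 ± 0.20) and Enc1 (-0.95 ± 0.20). Adjusted p of these genes ran from 3.24e-07 to 0.0479.

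Of 34 Treg signature genes 15 rose and 0 fell (23 rose when adjusted over the list alone), with a median of 1.22 (adjusted p = 1.00e-17), and the list held with an estimated correlation (adjusted p = 0.0452). The conventional T cell list was called lower, with a mean of -0.15 but a median of 0.0505, and 1 member, Il7r, fell (adjusted p = 0.395 with an estimated correlation). Th1, follicular helper and cytotoxic genes were called lower with medians of -0.0412, -0.28 and -0.20. None of their members fell past the threshold and Gzmb, of the cytotoxic list, rose (1.27 ± 0.24). These calls were lost with an estimated correlation, with adjusted p = 0.0816, 0.28 and 0.395. The follicular helper and cytotoxic calls also ended with both normalizations (adjusted p from 0.168 to 0.199), and the block ended the follicular helper call (adjusted p = 0.101). With the block, immediate early genes were called higher (median 0.58, camera adjusted p = 0.00368), against adjusted p = 0.602 without it. In CD25+ and CD25- arrays the list averaged 10.96 and 10.90 (replicate 1), 11.02 and 10.80 (replicate 2) and 10.76 and 9.51 (replicate 3). Most of the shift thus lay in the replicate 3 pair, whose CD25- array was dim. An estimated correlation was not tried with the block. Myeloid and dendritic markers lay higher in CD25+ arrays (median 0.84), where 0 of 21 passed over all genes and 8 when adjusted over the list alone (adjusted p = 0.842 with an estimated correlation). Lyz2 averaged 8.80 ± 1.30 in CD25+ and 7.24 ± 0.56 in CD25- arrays, Csf1r 10.45 ± 0.56 and 9.61 ± 1.41, and the B cell gene Ms4a1 7.79 ± 0.15 and 6.98 ± 0.58. Whether RNA of host cells enters the DEC differences, H2-Ob among them, was not tested.

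The count moved with single arrays and was 222 without DEC CD25+ replicate 1, 19 without DEC CD25+ replicate 2, 24 without DEC CD25+ replicate 3, 330 without DEC CD25- replicate 1 and 115 without DEC CD25- replicate 2. It was 5 when the 7 arrays were fitted alone. Without both dim CD25- arrays 53 genes were called, 22 higher and 31 lower, and only 29 of the 62 calls were kept.

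Across the 3 Treg-partner comparisons, which share no arrays, 15 genes were called in the same direction in each, with 0.0053 higher and 0.0016 lower expected if the calls were independent. The calls are not independent, as all 3 comparisons used the same pooled spread of each gene. The expected numbers and exact p can therefore overstate the overlap. The 10 higher genes were Il2ra, Itih5, Foxp3, Gpr83, Neb, Ikzf4, Tnfrsf9, Phlpp1, Slc2a3 and Ikzf2. Cells were sorted by the Foxp3 reporter in the LP and homeostatic groups and by CD25 in the DEC groups. The place of Foxp3 and Il2ra among the shared genes was thus in part fixed by the sort. The 5 lower genes were Tdrp, Sema4a, Lypd6b, Il1rl2 and Enc1. LP and homeostatic comparisons shared 37 higher and 53 lower genes, where 1.33 and 1.62 were expected (Fisher's exact p = 7.07e-45 and 2.9e-69), and 3 genes higher in the first were lower in the second. LP and DEC comparisons shared 21 higher and 7 lower genes (0.707 and 0.154 expected; exact p = 2.04e-26 and 3.84e-11). Homeostatic and DEC comparisons shared 16 and 6 (0.376 and 0.121 expected; exact p = 1.08e-22 and 8.12e-10). Across all genes, which are not independent replicates, Pearson's correlation of the log2 fold changes was 0.39, 0.18 and 0.23 for these pairs. Spearman's was lower, at 0.25, 0.0249 and 0.12, so by rank LP and DEC changes hardly went together in these values. Most genes were called in neither comparison, and their ranks hold much noise. No correlation was computed without the dim arrays or after normalization, which moved the median of the DEC changes. The number shared by all 3 comparisons was 28 with the replicate block, 23 without both dim arrays and 1 when each comparison was fitted alone.

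**Figure D3:**
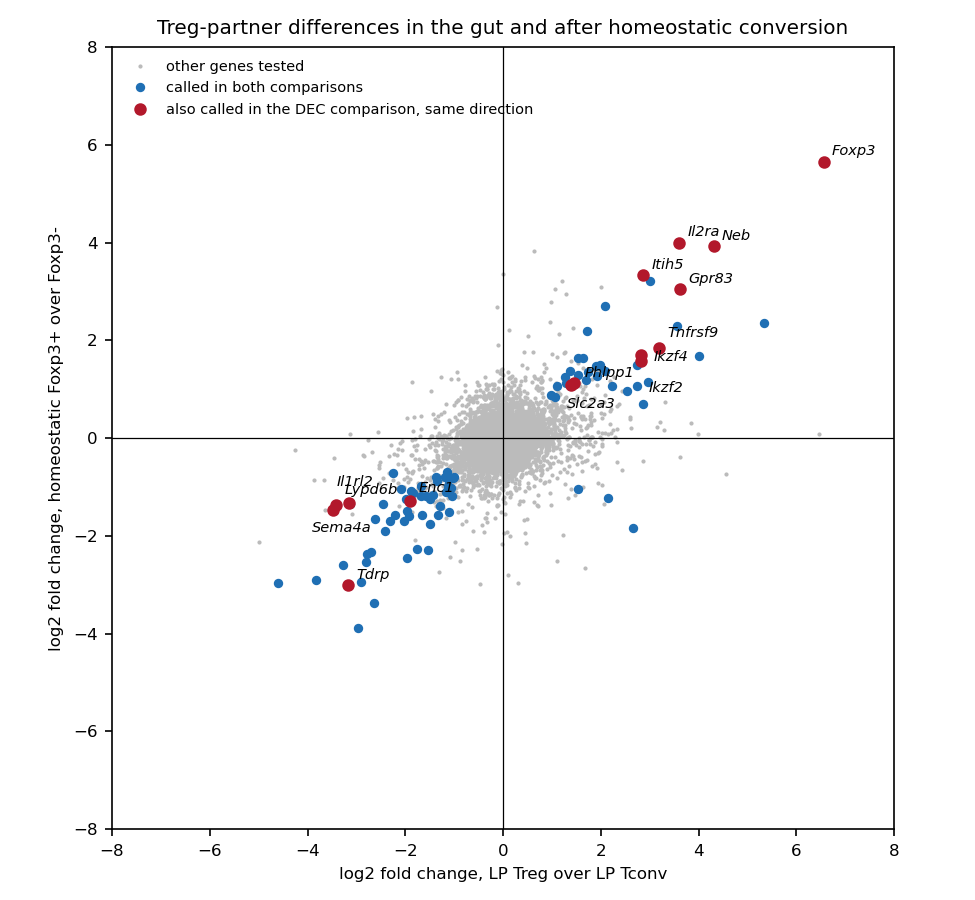
Log2 fold change of each tested gene for LP Treg over LP Tconv (x axis) against homeostatic Foxp3+ over Foxp3- (y axis), with genes called in both comparisons in blue and the 15 genes also called in the DEC comparison, in the same direction, in red with their names. Of the genes called in both, 37 lie at the upper right, 53 at the lower left and 3 at the lower right.

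The lymph node subsets asked how Treg cells that display CD103 and Klrg1 differ from those that do not. Between CD103+Klrg1- and CD103-Klrg1- cells, Itgae, the gene of the sort marker, was 26.2-fold higher (4.71 ± 0.61, n = 2 and 2 arrays, adjusted p = 0.00202). The secreted fibrinogen-like protein Fgl2, the granzyme Gzmb, the chemokine receptor Ccr2 and the gut homing receptor Gpr15 were higher by 2.80 ± 0.41, 2.60 ± 0.31, 2.58 ± 0.38 and 2.41 ± 0.38. Foxp3 and Il2ra differed by 0.48 ± 0.36 and 0.16 ± 0.38 and Klrg1 by 1.29 ± 0.41, none past the threshold, though Klrg1 was called with the replicate block (adjusted p = 0.0312).

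The test called 12 genes, 11 higher and 1 lower, where 255 had an unadjusted p under 0.05 and 626 are expected by chance. A count below chance means that p ran large with the spread pooled over all arrays, not that the subsets are alike. The count was 619 with these arrays fitted alone and 652 with array weights. The others named were Gbp2b (2.59 ± 0.39), Gcnt1 (2.22 ± 0.33), Rnase4 (2.13 ± 0.34), Gpr160 (1.69 ± 0.21) and Arnt2 (1.47 ± 0.26), and the 1 that fell was Ntn4 (-1.43 ± 0.24). Of 34 Treg signature genes 3 rose (8 when adjusted over the list alone; median 0.63, adjusted p = 1.18e-30), and of 23 effector and memory-like genes 3 rose (10 when adjusted over the list alone; median 0.86, adjusted p = 9.61e-36). Chemokine receptors moved up with Ccr2 and Gpr15 (adjusted p = 5.31e-12). Th17 and Th1 genes moved up with no member past the threshold, and 4 and 2 when adjusted over the list alone (adjusted p = 5.71e-06 and 0.000251). These 5 list calls held with an estimated correlation. Conventional and naive genes moved down (medians -0.51 and -0.43) with no member called, and were lost with an estimated correlation (adjusted p = 0.183 and 0.118). Cytotoxic genes, integrins, TNF receptor genes and glycolysis genes moved up, with Gzmb and Itgae the members called, and were lost with an estimated correlation as well (adjusted p = 0.272, 0.114, 0.0573 and 0.64). The glycolysis call ended with cyclic loess normalization (adjusted p = 0.0535).

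The number of called genes was 3 without LN Treg CD103-Klrg1- replicate 1, 0 without LN Treg CD103-Klrg1- replicate 2 and 1 without LN Treg CD103+Klrg1- replicate 2. At 0 calls, limma gave 140 genes an unadjusted p under 0.05, again fewer than chance gives. The count was 28 with cyclic loess normalization, 20 with a pseudocount of 16 and 28 without both dim DEC CD25- arrays.

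Between CD103+Klrg1+ and CD103+Klrg1- cells, Klrg1 was 38.3-fold higher (5.26 ± 0.41, n = 2 and 2 arrays, adjusted p = 2.24e-06). Anxa1, an anti-inflammatory annexin, Gzmb, galectin-3 (Lgals3) and the inhibitory receptor Havcr2, also named Tim-3, rose by 3.11 ± 0.33, 2.88 ± 0.31, 2.54 ± 0.41 and 2.28 ± 0.41. Gpr83 (-2.99 ± 0.35) and Plagl1 (-3.02 ± 0.47), both of the Treg signature list, fell, as did P2rx7, a receptor for extracellular ATP (-1.99 ± 0.36). Foxp3, Il2ra and Itgae differed by 0.37 ± 0.36, -0.16 ± 0.38 and 0.46 ± 0.61, none past the threshold.

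The test called 81 genes, 48 higher and 33 lower, 75 of them by at least 2-fold. The other named rises were Sv2c (3.05 ± 0.38), Snai2 (2.50 ± 0.35), Frmd5 (2.39 ± 0.25), Jcad (2.25 ± 0.32) and Slc15a3 (2.23 ± 0.37), and the other named falls Gbp2b (-2.82 ± 0.39), Hepacam2 (-2.74 ± 0.22), Gsta4 (-2.31 ± 0.32), Khdc1a (-2.23 ± 0.20), Gata1 (-2.05 ± 0.38), Sh3bgrl2 (-2.03 ± 0.34) and Hdgfl3 (-2.01 ± 0.30). Of 23 effector and memory-like genes 6 rose and 0 fell (11 rose when adjusted over the list alone; median 1.28, adjusted p = 5.63e-29). B cell markers moved up (median 0.67, adjusted p = 8.44e-09) with 0 members called and 2 when adjusted over the list alone. Both calls held with an estimated correlation. The Treg signature (3 rose, 2 fell), cytotoxic genes and chemokine receptors moved up, with Ccr10 (1.57 ± 0.23) and Cxcr6 (2.08 ± 0.46) among the receptors, and were lost with an estimated correlation (adjusted p = 0.504, 0.236 and 0.0798). Cell cycle, Th17, Th1 and myeloid genes moved up and naive genes down with no member called, and were lost with an estimated correlation (adjusted p = 0.343, 0.196, 0.196, 0.614 and 0.236). The call of the Th1 genes ended with quantile normalization (adjusted p = 0.0511). The myeloid call rested on CD103+Klrg1+ replicate 2 and ended without it (adjusted p = 0.897). Myeloid markers averaged 8.06 on that array, 7.35 in replicate 1, and 7.33 and 7.17 in CD103+Klrg1- arrays. The array was also higher than replicate 1 in B cell markers (9.17 against 8.48), CD8 T and NK markers (7.03 against 6.05) and Hspa1b (10.04 against 7.09). Leaving out 1 array ended 7 of the 10 list calls.

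With 1 array left out the count was 25 without LN Treg CD103+Klrg1- replicate 1, 33 without LN Treg CD103+Klrg1- replicate 2, 35 without LN Treg CD103+Klrg1+ replicate 1 and 47 without LN Treg CD103+Klrg1+ replicate 2. It was 134 without both dim DEC CD25- arrays.

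Between the outer subsets, CD103+Klrg1+ and CD103-Klrg1-, the differences were larger. Klrg1 was 93.9-fold higher (6.55 ± 0.41, n = 2 and 2 arrays), Gzmb 44.6-fold (5.48 ± 0.31) and Itgae 36.1-fold (5.17 ± 0.61), and Fgl2 and Ccr2 rose by 4.17 ± 0.41 and 3.92 ± 0.38. Bcl2, which protects cells from apoptosis (-2.73 ± 0.51), fell along with Gpr83 (-3.57 ± 0.35), Khdc1a (-3.23 ± 0.20), Ntn4 (-3.12 ± 0.24) and Tubb2a (-2.68 ± 0.50). Adjusted p of these genes ran from 2.08e-08 to 0.00423. Foxp3 and Il2ra differed by 0.84 ± 0.36 and 0.0062 ± 0.38, neither past the threshold.

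The test called 263 genes, 184 higher and 79 lower, 249 by at least 2-fold. Of 23 effector and memory-like genes 14 rose and 0 fell (19 rose when adjusted over the list alone), with a median of 2.04 (adjusted p = 4.06e-47). Among 34 Treg signature genes 9 rose, while Gpr83 and Plagl1 (-2.43) fell (adjusted p = 1.91e-15). Of 15 chemokine receptors 5 rose, for example Cxcr6 (2.94 ± 0.46), Gpr15 (2.78 ± 0.38) and Ccr10 (1.94 ± 0.23) (adjusted p = 5.36e-11). Of Th17 genes the transcription factors Ahr (2.46 ± 0.41), Rora (2.13 ± 0.36) and Maf (1.98 ± 0.40) rose (adjusted p = 1.64e-07), and of Th1 genes Cxcr3 (1.88 ± 0.41) and Il18r1 (1.60 ± 0.27) (adjusted p = 3.10e-05). In the naive and central list Bcl2, Bach2 (-2.05) and Igfbp4 (-1.77) fell and Il7r rose (1.07 ± 0.23; adjusted p = 3.70e-07). B cell markers moved up (median 0.71, adjusted p = 3.10e-05) with no member called. These 7 list calls held with an estimated correlation, the last 2 narrowly (adjusted p = 0.0449 and 0.0488). The B cell call ended without CD103+Klrg1+ replicate 2 (adjusted p = 0.239).

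Other list calls between the outer subsets were lost with an estimated correlation. Conventional genes moved down (adjusted p = 0.173 with an estimated correlation), with Il7r of this list higher. Cell cycle genes moved up with Prc1 (1.57 ± 0.29) as the 1 member called (adjusted p = 0.346 with an estimated correlation). Cytotoxic genes, integrins and TNF receptor genes moved up with Havcr2 (3.75 ± 0.41) and Cd44 (1.67 ± 0.34) among their called members (adjusted p = 0.15, 0.196 and 0.196 with an estimated correlation). The number of called genes was 149 without LN Treg CD103-Klrg1- replicate 1, 124 without LN Treg CD103-Klrg1- replicate 2 and 127 without LN Treg CD103+Klrg1+ replicate 1, and 398 without both dim DEC CD25- arrays.

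LP Treg with CD103-Klrg1- lymph node Treg arrays compared Treg cells of the gut with those of the lymph nodes that lack both markers. Il10 was 121-fold higher in LP Treg cells (6.92 ± 0.50, n = 2 and 2 arrays, adjusted p = 1.85e-07), and the granzymes Gzmb and Gzma 115-fold (6.84 ± 0.31) and at least 66.8-fold (6.06 ± 0.42). Klrg1, Itgae and Fgl2 rose by 5.77 ± 0.41, 4.92 ± 0.61 and 5.05 ± 0.41, and the heat shock genes Hspa1b and Hspa1a by 5.42 ± 0.82 and 5.18 ± 0.46. Lymph node Treg arrays held more Bach2, a repressor of effector genes (-3.17 ± 0.50), and more Bcl2 (-3.15 ± 0.51). They also held more of the B cell genes Ms4a1, which encodes CD20 (-3.40 ± 0.39), Pou2af1 (-3.17 ± 0.49) and Bank1 (-3.08 ± 0.53). Whether the B cell genes came from the Treg cells or from B cell RNA stays open. Foxp3 and Il2ra differed by 0.86 ± 0.36 and -1.14 ± 0.38, neither past the threshold, though Il2ra was called with the replicate block (adjusted p = 0.0343). That block rests on an assumed pairing of gut with lymph node arrays.

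The test called 570 genes, 304 higher and 266 lower in LP Treg cells, 511 by at least 2-fold. The other named rises were Mmp9 (4.35 ± 0.33) and Rnase4 (4.21 ± 0.34), and the other named falls Cnn3 (-4.34 ± 0.66), Pxylp1 (-3.90 ± 0.39), Sema4a (-3.85 ± 0.42), Cmah (-3.29 ± 0.51) and Tubb2b (-3.29 ± 0.85). Of 23 effector and memory-like genes 12 rose, with Ccr2 (4.13 ± 0.38) and Id2 (3.96 ± 0.38) (adjusted p = 2.99e-15), and of 15 chemokine receptors 8 rose, with Gpr15 (3.01 ± 0.38) and Cxcr6 (2.97 ± 0.46) (adjusted p = 3.55e-08). Of 16 naive and central genes 7 fell, with Il6ra (-2.63 ± 0.47) and Foxp1 (-2.11 ± 0.34) (adjusted p = 3.55e-08). Of Th1 genes Ifng (2.24 ± 0.41), Cxcr3 (2.17 ± 0.41), Il18rap (1.94 ± 0.30) and Il18r1 (1.15 ± 0.27) rose, and of Th17 genes Maf (2.53 ± 0.40), Ahr (2.44 ± 0.41), Rora (2.27 ± 0.36) and Il1r1 (1.20 ± 0.19) (adjusted p = 3.10e-07 and 9.17e-07). The Th2 list moved up with its chemokine receptors Ccr4 (2.14 ± 0.23) and Ccr8 (1.21 ± 0.31) (adjusted p = 0.000306).

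Markers of other cells also differed between the sites. Of 10 B cell markers 4 fell in LP Treg arrays (6 when adjusted over the list alone; median -0.82, adjusted p = 9.58e-06). Of 6 plasma cell markers 2 rose: Jchain, which joins antibody monomers, averaged 10.44 ± 0.66 in LP Treg, 9.46 ± 0.79 in LP Tconv and 6.43 ± 0.17 in the lymph node arrays, and Igha, the IgA heavy chain, 11.20 ± 1.56, 10.21 ± 0.34 and 7.43 ± 0.11 (adjusted p = 0.00218). Of 10 heat shock genes 3 rose (median 0.54, adjusted p = 0.000155), and Hspa1a averaged 9.64 ± 0.10 in LP Treg, 10.68 ± 0.38 in LP Tconv and 4.46 ± 0.41 in the lymph node arrays. All 9 list calls so far held with an estimated correlation.

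Lost with an estimated correlation were the Treg signature, in which 13 members rose and 3 (Ikzf4, -1.52; Nrp1, -1.76; Plagl1, -2.14) fell (adjusted p = 0.065), and the conventional genes, in which 7 fell and Nrip1 rose (adjusted p = 0.143). The TNF receptor list had 5 rises, with Tnfrsf1b (2.75 ± 0.39) and Havcr2 (2.65 ± 0.41) (adjusted p = 0.0673 with an estimated correlation). Immediate early genes moved up by a median of 1.36, with 4 of 28 called and 12 when adjusted over the list alone, for example Rel (2.64 ± 0.51) and Tnfaip3 (3.15 ± 0.67) (adjusted p = 0.262 with an estimated correlation). Cytotoxic, glycolysis and cholesterol synthesis genes moved up and CD8 T and NK markers down (adjusted p = 0.183, 0.473, 0.112 and 0.275 with an estimated correlation). The number of called genes was 194 without LP Treg replicate 1, 330 without LN Treg CD103-Klrg1- replicate 1 and 234 without LN Treg CD103-Klrg1- replicate 2. It was 1006 when the 4 arrays were fitted alone and 1082 without both dim DEC CD25- arrays.

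LP Treg with CD103+Klrg1+ lymph node Treg arrays compared gut Treg cells, sorted by GFP alone, with lymph node Treg cells sorted to carry both markers. Foxp3, Itgae and Klrg1 differed by 0.016 ± 0.36, -0.26 ± 0.61 and -0.78 ± 0.41 and Il2ra by -1.15 ± 0.38, none past the threshold. With the replicate block, which assumes that gut and lymph node arrays pair by number, Klrg1 was called lower in LP Treg cells (adjusted p = 0.0474). The small intestinal homing receptor Ccr9 was 41.2-fold higher in LP Treg cells (5.36 ± 0.60, n = 2 and 2 arrays, adjusted p = 4.17e-05), Gzma 31.8-fold (4.99 ± 0.42) and Il10 15-fold (3.91 ± 0.50). Hspa1a, Hspa1b and Jchain rose by 4.64 ± 0.46, 4.10 ± 0.82 and 3.98 ± 0.43. These genes were also high in LP Tconv arrays (10.68, 12.76 and 9.46), and whether plasma cell RNA brought Jchain was not tested. The lymph node arrays held more Anxa1 (-3.84 ± 0.33) and Pxylp1 (-3.94 ± 0.39). They also held more of the B cell genes Ms4a1 (-4.13 ± 0.39), Bank1 (-3.73 ± 0.53) and Pou2af1 (-3.70 ± 0.49), whose source stays open.

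The test called 257 genes, 93 higher and 164 lower, 237 by at least 2-fold. Of 10 B cell markers 6 fell (8 when adjusted over the list alone; median -1.50, adjusted p = 3.51e-13), and this call held with an estimated correlation. Effector and memory-like genes moved down, with S100a4 (-3.03 ± 0.49) and Lgals3 (-2.33 ± 0.41) fallen and Bhlhe40 (3.66 ± 0.61) and Gzmb (1.36 ± 0.31) risen, and the call was lost with an estimated correlation (adjusted p = 0.579) and with cyclic loess normalization (adjusted p = 0.101). Plasma cell, heat shock and Th2 lists moved up, the last with Gfi1 (2.00 ± 0.42) and Ccr4 (1.36 ± 0.23), and were lost with an estimated correlation (adjusted p = 0.0728, 0.0728 and 0.0728). Immediate early genes (2 of 28 rose, Rel (2.88 ± 0.51) and Tnfaip3 (2.83 ± 0.67)), Th1 genes (Stat4 (1.82 ± 0.45)), cholesterol synthesis genes and stromal markers moved up and were lost as well (adjusted p = 0.357, 0.142, 0.0908 and 0.357 with an estimated correlation). Naive, cell cycle, myeloid and CD8 T and NK lists moved down and were lost (adjusted p = 0.357, 0.689, 0.579 and 0.322 with an estimated correlation). Without CD103+Klrg1+ replicate 2 the naive, myeloid and CD8 T and NK calls ended (adjusted p = 0.576, 0.401 and 0.243).

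The number of called genes was 95 without LP Treg replicate 1, 152 without LN Treg CD103+Klrg1+ replicate 1 and 117 without LN Treg CD103+Klrg1+ replicate 2. It was 448 without both dim DEC CD25- arrays.

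**Figure D4:**
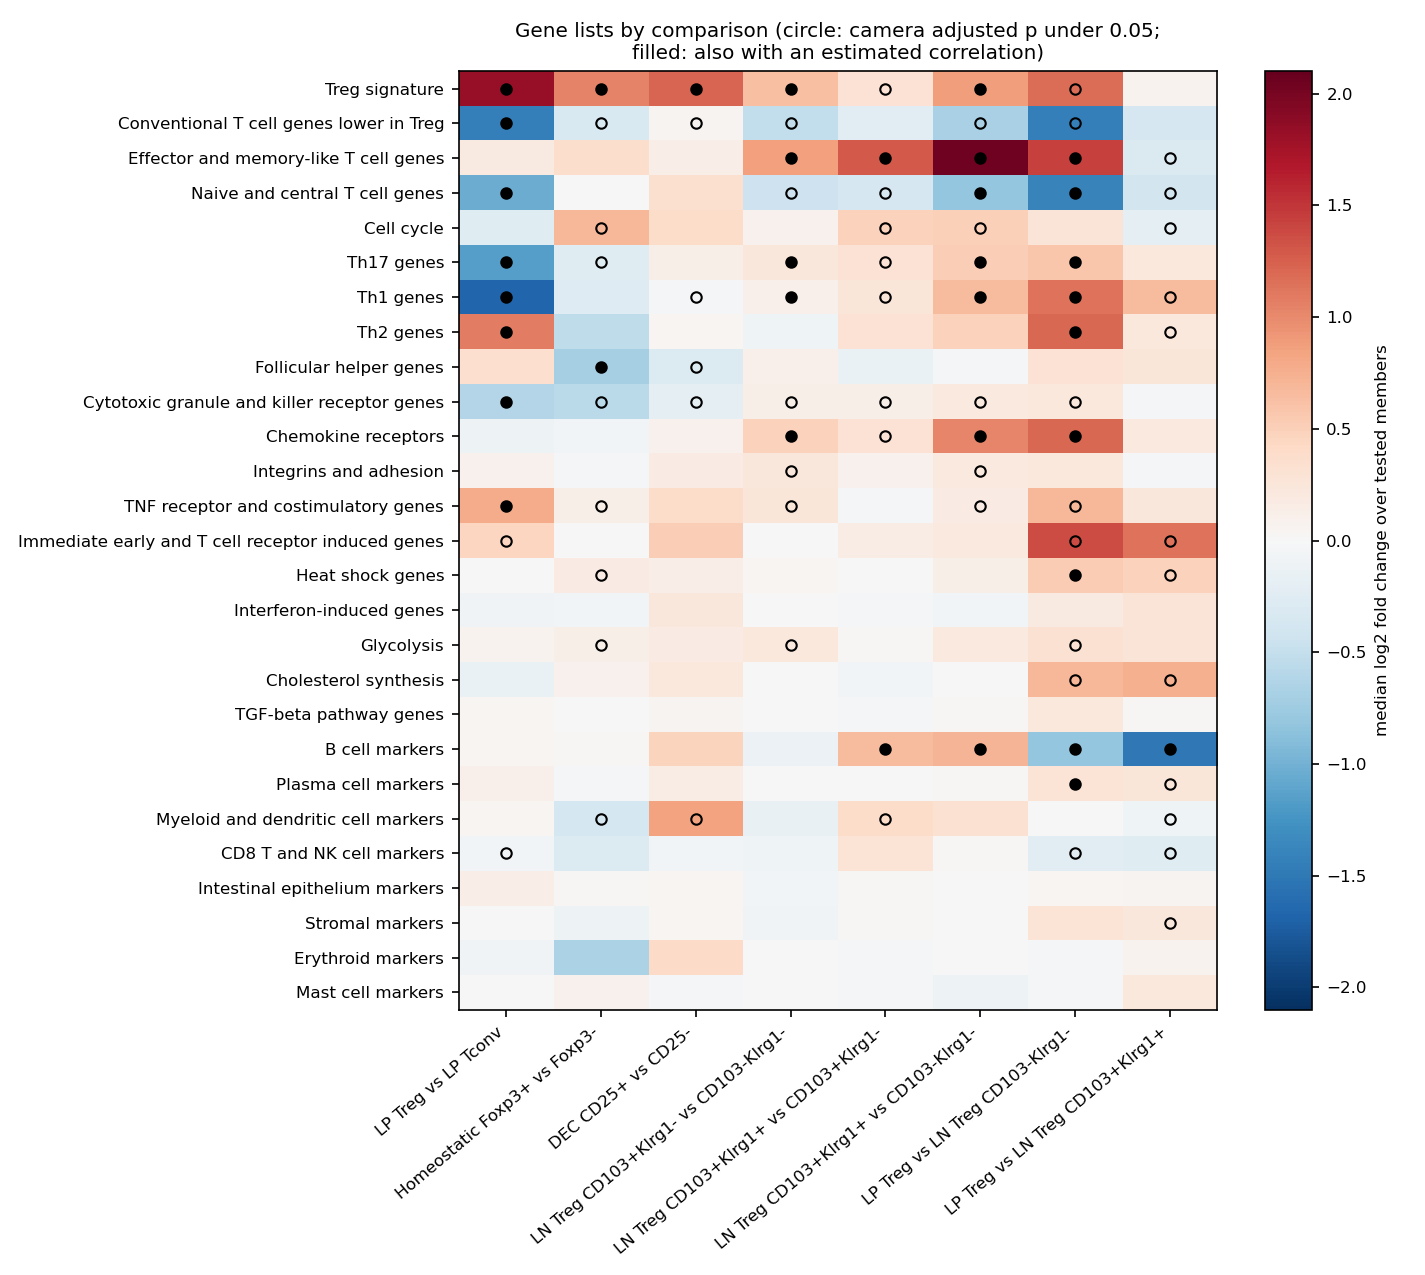
Median log2 fold change over the tested members of each of the 27 gene lists (y axis) in each of the 8 comparisons (x axis) as colour, with an open circle where camera passed the threshold at the preset correlation and a filled one where it also passed with an estimated correlation. Of 216 tests 89 carry a circle and 35 a filled one; the darkest red is the effector and memory-like list between the outer lymph node subsets (2.04).

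Interferon-induced genes, TGF-beta pathway genes and the markers of intestinal epithelium, erythroid and mast cells passed the camera threshold in none of the 8 comparisons without the replicate block. Their smallest adjusted p were 0.137, 0.0539, 0.406, 0.175 and 0.279.

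Each gene was read from 1 probe set, and other probe sets of the same gene did not always move with it. Named and called genes had 125 other probe sets above the filter, which gave 233 values over the comparisons; 52 had an unadjusted p of 0.05 or more and 6 the opposite sign. Those of opposite sign were of Tgfbr3 for LP Treg with LP Tconv (0.26), Tnfrsf1b between the outer lymph node subsets (-0.22), and Ikzf4, Igfbp4, Themis and Il6ra for LP Treg with CD103-Klrg1- cells (0.009, 0.0666, 0.13 and 0.20), none with an unadjusted p under 0.05. For Ahr the other probe set differed by 0.0474 between the outer subsets and by 0.17 for LP Treg with CD103-Klrg1- cells. For homeostatic Ighm 1 of 4 others moved along (3.81) and 3 differed by 0.17, 0.0576 and 0.0361, and for DEC Enc1 and Ldlrad4 1 other each by -0.0185 and -0.0661.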

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

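Both tests of Foxp3 in the DEC CD25- arrays were chosen after the result was seen. The Treg-partner difference itself differed between systems in a number of genes, by the test of the interaction. Between the LP and the homeostatic difference 97 genes were called (70 more positive in the LP). The LP difference lay more positive for Itgb8 by 6.37 ± 0.62, Matn2 by 4.50 ± 0.43, Ky by 3.52 ± 0.32, Arfgef3 by 3.27 ± 0.35 and Klrg1 by 3.00 ± 0.53, and lay lower for Il17a (-4.00 ± 0.42). Adjusted p ran from 3.62e-05 to 0.00706.

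Between the LP and the DEC difference 126 genes were called, 51 with the LP difference more positive and 75 less. With quantile and cyclic loess normalization these became 69 and 50, and 80 and 69. Klrg1 (4.18 ± 0.52), Foxp3 (4.07 ± 0.46), Ky (3.71 ± 0.31) and Ppm1l (2.68 ± 0.30) lay higher in the LP difference, and Il17a (-4.32 ± 0.41) and Ryr1 (-2.81 ± 0.29) lower. Between the homeostatic and the DEC difference 42 genes were called, 10 more positive and 32 less, and 24 and 36, and 26 and 31, with these normalizations. With the replicate number as a block the test called 138, 34 more positive and 104 less. Klrg1 (1.11, adjusted p = 0.0479) was then called as well. Foxp3 (3.17 ± 0.41) lay higher in the homeostatic difference, and Arfgef3 (-3.24 ± 0.31), Tnfsf14 (-3.12 ± 0.35), Ryr1 (-2.86 ± 0.25), Epas1 (-2.56 ± 0.32) and Lbp (-1.68 ± 0.20) lower. The systems also differ in strain, T cell receptor, host, site, sort and the levels of Xist and Y-linked genes, and no test separates these.

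Single arrays stood apart within the DEC CD25- group in 2 of 27 genes tested, where chance gives about 1 in 20. Foxp3 was 6.92 in replicate 1 and from 8.23 to 8.48 in the other 3 arrays, and Ldlrad4 was 6.11 in replicate 4, apart from its group.

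Foxp3 in the DEC CD25- arrays lay between the CD25+ arrays and the arrays of Foxp3-GFP- cells. If CD25+ cells left in the CD25- sort were the whole source, they would have to make up 6.83%, 23.8%, 20.3% and 19.7% of the RNA of the 4 arrays. Il2ra, which such cells would bring along, allows at most 5.36%, 12.1%, 7.71% and 5.25%, below the need in 4 of 4 arrays. The need takes off the Foxp3 background of the Foxp3-GFP- arrays, which are of other strains. If that background holds, the values argue against carry-over of average CD25+ cells as the whole source, narrowly in replicate 1. A strain difference in the background of the Foxp3 probe set stays open: 0 other probe sets for Foxp3 are named, and no array holds Balb/c cells sorted as Foxp3-. Foxp3 in cells with little CD25, which the sort by CD25 allows, may also account for it and was not tested.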

How the results depend on the processing

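Leaving out both dim DEC CD25- arrays was chosen after the data were seen; all other alternatives were planned. Leaving out 1 array cannot reverse a gene whose arrays do not overlap between the groups. The filters, the prior and the fit on a comparison's own arrays leave the fold change itself unchanged. It was thus largely fixed beforehand that, of 308 single results named and called, 0 changed direction under any alternative. Those no longer past the threshold numbered 85 when each comparison was fitted on its own arrays, 16 with no filter, 13 of 297 with the mean of probe sets, 10 with quantile normalization and 0 to 9 under each other alternative, and 372 of 1534 over all arrays left out in turn. Counts within 1.5 times the reported one under an alternative are not given; for the rest the cause was not tested. Counts were 28 with cyclic loess normalization and 20 with a pseudocount of 16 (CD103+Klrg1- with CD103-Klrg1-). On each comparison's own arrays, which alone then gave the spread, they were 17 (LP), 741 (homeostatic), 5 (DEC), 1006 (LP Treg with CD103-Klrg1-), 26 (LP against DEC) and 1 (shared). The count fell for LP and rose for LP Treg with CD103-Klrg1-, both of 2 with 2 arrays. The smaller number of arrays thus does not by itself explain these changes. With array weights they were 221 (LP), 1236 (homeostatic), 193 (DEC), 99 (CD103+Klrg1- with CD103-Klrg1-), 264 (CD103+Klrg1+ with CD103+Klrg1-), 599 (CD103+Klrg1+ with CD103-Klrg1-), 1494 (LP Treg with CD103-Klrg1-), 648 (LP Treg with CD103+Klrg1+), 80 (LP against DEC), 292 (homeostatic against DEC) and 31 (shared). With the replicate block they were 615 (LP), 480 (homeostatic), 139 (DEC), 27 (CD103+Klrg1- with CD103-Klrg1-), 136 (CD103+Klrg1+ with CD103+Klrg1-), 453 (CD103+Klrg1+ with CD103-Klrg1-), 959 (LP Treg with CD103-Klrg1-), 451 (LP Treg with CD103+Klrg1+), 217 (LP against homeostatic), 245 (LP against DEC), 138 (homeostatic against DEC) and 28 (shared); same-number residuals correlated at -0.07 for LP and from 0.37 to 0.72 for the lymph node groups. Without both dim arrays they were 557 (LP), 435 (homeostatic), 28 (CD103+Klrg1- with CD103-Klrg1-), 134 (CD103+Klrg1+ with CD103+Klrg1-), 398 (CD103+Klrg1+ with CD103-Klrg1-), 1082 (LP Treg with CD103-Klrg1-), 448 (LP Treg with CD103+Klrg1+), 179 (LP against homeostatic) and 23 (shared). Of 24 named results not called, the block made 6 pass: Itgae for LP (adjusted p = 0.00458), Klrg1 for DEC (adjusted p = 0.0057), CD103+Klrg1- with CD103-Klrg1- (adjusted p = 0.0312), LP Treg with CD103+Klrg1+ (adjusted p = 0.0474) and homeostatic against DEC (adjusted p = 0.0479), and Il2ra for LP Treg with CD103-Klrg1- (adjusted p = 0.0343). Array weights made this Il2ra result (adjusted p = 0.0326) and Klrg1 for DEC (adjusted p = 0.0185) pass. Leaving out 1 array ended 33 of the 89 list calls, 2 of them among the 35 that held with an estimated correlation. List calls numbered 35 with an estimated correlation and 47 with fry.

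Leaving out 1 array in turn, where a lone array of a group is assumed to vary like the other groups, the counts ran over 173 to 513 (LP), 133 to 173 (homeostatic), 19 to 330 (DEC), 0 to 8, 25 to 47 and 124 to 201 (the lymph node pairs in the order above), 194 to 438 and 95 to 194 (LP Treg with the lymph node subsets), 55 to 157, 45 to 396 and 21 to 77 (the interactions), 11 to 20 (shared) and 82 to 93 (lists). Interaction counts beyond 1.5 times came from LP against homeostatic (55 without LP Treg replicate 1, 57 without LP Treg replicate 2, 157 without LP Tconv replicate 1), LP against DEC (45 without LP Treg replicate 1, 83 without LP Treg replicate 2, 396 without LP Tconv replicate 1, 80 without LP Tconv replicate 2, 82 without DEC CD25+ replicate 2) and homeostatic against DEC (26 without Homeostatic Foxp3+ replicate 1, 21 without Homeostatic Foxp3+ replicate 3, 25 without DEC CD25+ replicate 2, 24 without DEC CD25+ replicate 3, 27 without Homeostatic Foxp3- replicate 3, 77 without DEC CD25- replicate 1, 66 without DEC CD25- replicate 2). The values that changed sign were of uncalled sort genes. For CD103+Klrg1+ with CD103-Klrg1-, Il2ra became -0.0823 with the mean of probe sets, -0.0103 with cyclic loess and -0.33 to 0.34 with 1 array left out. For LP against DEC it became 0.14 with cyclic loess, 0.0039 without both dim DEC CD25- arrays and -0.56 to 0.23 with 1 array left out. With 1 array left out, Il2ra ran from -0.79 to 6.19e-05 for LP against homeostatic, from -0.0038 to 0.33 for CD103+Klrg1- with CD103-Klrg1-, from -0.49 to 0.18 for CD103+Klrg1+ with CD103+Klrg1- and from -0.0255 to 0.43 for homeostatic against DEC. For LP Treg with CD103+Klrg1+, Foxp3 became -0.0274 with quantile normalization and -0.29 to 0.32 with 1 array left out. For homeostatic against DEC, Itgae became -0.004 with array weights and -0.35 to 0.74 with 1 array left out. Genes near the floor limit the fold changes, which are then compressed by background.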

Other observations

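The B cell test with Ighm left out, the demand that B cell genes pass a bound by a standard error, and the splits that part all pairs were chosen after the results were seen, and the tests of overlap with the lymph node subsets after lists of the called genes had been seen; the other tests of this part were chosen before. Mki67, a marker of dividing cells, averaged 11.92 ± 0.055 in homeostatic Foxp3+ and 10.94 ± 0.71 in homeostatic Foxp3- arrays, 10.48 ± 0.44 in LP Tconv, 10.01 ± 0.29 in LP Treg and 8.14 ± 1.29 in DEC CD25+ arrays. Tested myeloid and dendritic markers averaged from 8.51 to 10.40 per homeostatic array, and 6.98 and 7.23 in LP Tconv arrays. Erythroid markers were at 9.70 and 10.39 in both homeostatic arrays numbered 2 and at 6.88 and 7.86 in those numbered 1. Whether host cells brought the myeloid and erythroid transcripts was not tested.

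Genes higher in CD103+Klrg1+ than in CD103-Klrg1- lymph node Treg cells were tested for overlap with the Treg-partner comparisons, as a hypothesis that these subsets share a programme. Of 184 genes 20 were also higher in homeostatic Foxp3+ cells, 1.38 expected (Fisher's exact p = 4.11e-18), 56 in LP Treg cells, 2.6 expected (exact p = 4.04e-61), and 6 in DEC CD25+ cells, 0.735 expected (exact p = 8.64e-05). Lower there were 11, 11 and 1, with 1.85, 2.37 and 0.176 expected (exact p = 2.41e-06, 2.53e-05 and 0.163). Of genes lower in the subset, 6, 13 and 0 were lower in homeostatic Foxp3+, LP Treg and DEC CD25+ cells (exact p = 0.000141, 2.06e-11 and 1), and 5, 9 and 5 higher, with 0.593, 1.12 and 0.316 expected (exact p = 0.000312, 1.62e-06 and 1.5e-05). Overlap beyond the expected number was thus not limited to genes that moved the same way. Sort genes are among the shared ones. All these calls used the same pooled spread of each gene, so the exact p can overstate the overlap.

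Other splits of the arrays were counted for groups of at least 3. The 10 splits of the 6 homeostatic arrays are too few for a share under 0.05; the real split called 220 genes and the highest other 0. Of the 35 splits of the 7 DEC arrays, 7 called at least the 62 genes of the real one, so chance cannot be excluded from all splits. The highest other, 1260, grouped CD25+ replicate 3 with CD25- replicates 3 and 4, against the arrays numbered 1 and 2. CD25+ replicate 3 was not dim (median 79.3). In these 3 arrays the 3' Actb probe set exceeded the 5' one by 3.39, 4.04 and 3.63, the most of the DEC arrays. Dimness, RNA quality and replicate number cannot be told apart here. Among the 8 splits that part all 3 pairs the real one called 62 and the highest other 4. With the block the real one called 139, and the highest of the others, of 4 once a split and its mirror count as 1, called 0. These splits are again too few for a share under 0.05, so they do not exclude chance.

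Xist was high on all 7 DEC arrays (mean 12.66, against 7.03 on the other 16), though all mice were labelled male. Over the Y-linked genes Eif2s3y, Kdm5d and Uty the median of DEC minus other arrays was -3.30, and in 2 of the 3 genes every DEC array lay below every other array. That argues against male cells that express Xist and against a strain difference at the Xist probe set alone, and RNA of female cells may account for Xist. Eif2s3y was at 2.96 and 2.89 in both arrays numbered 1 and from 7.64 to 9.21 in the other 5, so female RNA alone does not cover those 5, and whether sexes were mixed was not tested.

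B cell markers were lower in LP Treg than in CD103-Klrg1- lymph node Treg arrays (median -0.82), although B220+ cells were sorted out. B cell RNA in the lymph node arrays would leave the homeostatic Foxp3+ arrays, from hosts without B cells, lower by over 1. Their median was -0.74, between the bounds set, so this stays open. The bound was hard to reach, as Pax5 (6.43), Cr2 (6.85) and Blnk (6.97) lay near the filter in the lymph node arrays already. Ms4a1 (-2.68), Bank1 (-2.04), Fcer2a (-1.36) and Cd79b (-1.10) were lower by over 1, while Cd22 (-0.0864) and Ighm (0.49) were not. In the homeostatic Foxp3+ arrays 7 of the 10 markers lay above the filter. The filter is the median of all values, so this is in itself no sign of expression. A difference between the Treg cells themselves would spare Cd79a, Cd79b and Ighm, by a bound of -0.5 on their median. It was -0.43 (Cd79a -0.70, below the filter; Cd79b -0.43 ± 0.50; Ighm 1.53), within 1 standard error of the bound, so this stays open too. Plasma cell genes were higher in the LP arrays and could raise Ighm, and Cd79b alone, at -0.43, does not decide. Ms4a1 was at 9.63 in the lymph node, 6.23 in the LP and 6.95 in the homeostatic Foxp3+ arrays.

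Heat shock genes were higher in LP Treg than in CD103-Klrg1- lymph node Treg arrays (median 0.54) and differed by a median of 0.0051 between LP Treg and LP Tconv arrays, so isolation from the gut wall and other effects of the site cannot be told apart, as no lymph node cells were isolated that way.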
